A study of Mus musculus with 12 samples.

How the data were processed

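Gene expression was measured on Affymetrix oligonucleotide arrays in white adipose tissue of male C57/BL6 mice, aged 6 to 8 weeks per the labels. The 12 arrays fall into 4 groups of 3: control and cold at 1 week (control_1wk, cold_1wk) and control and cold at 5 weeks (control_5wk, cold_5wk), with replicates numbered as in the titles. Per the labels, mice lived at 22 °C, were adapted to 18 °C for 1 to 3 weeks, and were then moved to 4 °C or kept as controls. For each array 5 µg of total RNA was amplified and labelled with biotin.

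The authors deposited 1 table of log2 signals, 1 value per probe set and array, made with GCRMA as named in the submitters' processing notes; GCRMA corrects background, normalizes between arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here. The table held 45101 probe sets, 64 of them controls, for 12 arrays, with 0 missing values. Array medians were 4.79 to 4.89, upper quartiles 7.57 to 7.80, and 56.7% to 58.4% of probe sets lay above log2 4. Each array correlated with the others of its group at a mean r of 0.992 to 0.998. The number of arrays limits the precision.

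A gene symbol was taken from the array annotation and updated through the gene identifier. Of the probe sets, 34958 named 1 gene (34754 of them updated), 932 several and 9211 none; the last 2 kinds were left out of the gene tests and are counted in the closing section. A probe set had to exceed log2 4 on at least 3 arrays, which 26545 did. For each gene the probe set with the highest mean over the 12 arrays was kept, which gave 12856 genes of 18194 on the array; 5681 of them had more than 1 probe set above the filter. In 397 of these genes at 1 week and 114 at 5 weeks, probe sets of the same gene were called in opposite directions.

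Changes were tested in R 4.3.3 with limma 3.58.1. lmFit and eBayes were run on 4 group means over all 12 arrays, with 2-sided moderated tests, and p-values were adjusted by Benjamini-Hochberg over the genes of each contrast at 0.05. The contrasts were cold against control at 1 week, at 5 weeks and averaged over both, the difference of the 2 cold effects (interaction), and 5 weeks against 1 week in cold and in control. For Elovl3, and for a gene whose signal was below log2 4 on all arrays of a group, the fold is given as at least the ratio with signals below 4 set to 4. Overlaps of calls were compared with the number given by unrelated lists, and the fold changes of both times were correlated across genes.

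A total of 26 gene lists was fixed from textbook knowledge, not from these samples: thermogenic and brown or beige adipocyte genes, fatty acid oxidation, oxidative phosphorylation, tricarboxylic acid cycle and pyruvate dehydrogenase, fatty acid and triglyceride synthesis, lipolysis and lipid droplet, white adipocyte identity and adipokines, angiogenic factors and receptors, endothelial markers, pericyte and smooth muscle markers, hypoxia response, macrophage markers, lymphocyte markers, skeletal muscle markers, epithelial, epididymal and mesothelial markers, cell cycle, creatine and calcium cycling, nerve and glia markers, extracellular matrix, erythrocyte transcripts, immediate early genes, heat shock and endoplasmic reticulum stress, circadian clock, antioxidant defence, interferon response and cholesterol synthesis. They were tested with camera in limma at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a contrast, and again with a correlation estimated per list. For the hypoxia (-0.003) and erythrocyte lists (-0.18) the estimate lay below the preset value. A larger correlation is therefore not why their adjusted p was higher with it. The rotation test fry was run as an alternative. It asks whether a list moves on balance, not whether it moves more than other genes. Counts below are of the members tested, which needed a probe set that names 1 gene and passes the filter. The epithelial, epididymal and mesothelial list kept 6 of 27 members, the erythrocyte list 4 of 11 and the nerve and glia list 11 of 22. Adrb3, Cpt1b, Plin1, Cfd and Acsl1 were among the listed genes not tested.

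The genes named for the 1 week and 5 week cold effects were the 10 largest rises and 10 largest falls among called genes whose 3 cold arrays all lay beyond the 3 control arrays, leaving out clone and locus names; a fixed set of 16 genes from Ucp1 to Pck1; and up to 4 members of each list with the smallest adjusted p. For the interaction they were the 5 highest and 5 lowest differences, and for the comparisons of weeks the 5 largest rises and falls. Members named outside this rule (Tmem26, Cox6a2, Atp5g1, Atp5g3, Cox7c, Pcx, Srebf1, Lox and, at 1 week, C1qa) were chosen after their values were seen, as the members that went against their list, and so were the clock and muscle genes given singly in the closing section. Comparisons, lists and these rules were chosen before the data were examined.

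The fit and the list test were run on simulated data of the same size, with 200 genes changed in each comparison by 1.5, 2 or 4-fold. The filter and the choice of probe set were not simulated. Of the 67 genes changed 2-fold the fit recovered 88.1% at 1 week, 80.6% at 5 weeks and 64.2% for the interaction. Of the 67 changed 1.5-fold it recovered 46.3%, 46.3% and 19.4%, and unchanged genes made up 5.68%, 7.34% and 4.65% of the calls. The noise was drawn for each gene on its own, without correlation between genes or differences in RNA quality between arrays. These shares check the fit and are not error rates of the real data.

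Alternatives chosen beforehand were other scalings of the arrays (centring on the median of all probe sets, quantile normalization), no filter, a filter at log2 6 and values below 4 set to 4. Also chosen beforehand were eBayes with trend and robust, all probe sets, the mean of the probe sets of a gene and only the arrays of the comparison. The last of these were array weights, replicate numbers as blocks, a 2-fold minimum and leaving out each array of the comparison. Chosen after seeing the data were covariates for the muscle list mean and for the 3' minus 5' signals of the Gapdh and of the Actb control probe sets, centring on the median of the tested genes, leaving out control_1wk 2 and 3, averaging the control_5wk arrays, leaving out genes raised on cold_1wk 2, and all alternatives to the interaction of single genes.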

Results

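White adipose tissue of male C57/BL6 mice was profiled on 12 Affymetrix expression arrays, 3 in each of 4 groups. Mice were kept in the cold at 4 °C or as controls, for 1 week or for 5 weeks. The labels give the control temperature in conflicting ways, as 30 °C in the titles and as room temperature in the source names, and they do not state the fat depot. They also do not state that the 3 arrays of a group came from separate animals, so the p-values measure the spread between these arrays, which may be technical. The deposited values were log2 signals, with array medians between 4.79 and 4.89, and 12856 genes were bright enough to test. The number of arrays limits the precision of every value below. For each gene the log2 fold change is cold over control unless stated otherwise, with its standard error (SE) from the limma model and n = 3 arrays per group.

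The first comparison asked what 1 week at 4 °C does to the tissue, in a study of cold exposure, browning of white fat and blood vessel growth. Ucp1, the uncoupling protein of brown and beige fat mitochondria, rose 201-fold (log2 7.65, SE 0.42). Elovl3, an enzyme of fatty acid elongation in brown fat, rose by log2 9.21 (SE 0.49), and at least 330-fold when signals below log2 4 were set to 4. Fabp3, a carrier of fatty acids in oxidative tissues, rose 54.1-fold (log2 5.76, SE 0.28), and Cox7a1, a subunit of cytochrome c oxidase, rose 36.5-fold (log2 5.19, SE 0.30). The largest fall was that of Nnat, an imprinted gene expressed in white adipocytes (log2 -2.86, SE 0.24). In all of these the 3 cold arrays lay beyond the 3 control arrays.

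**Figure D1:**
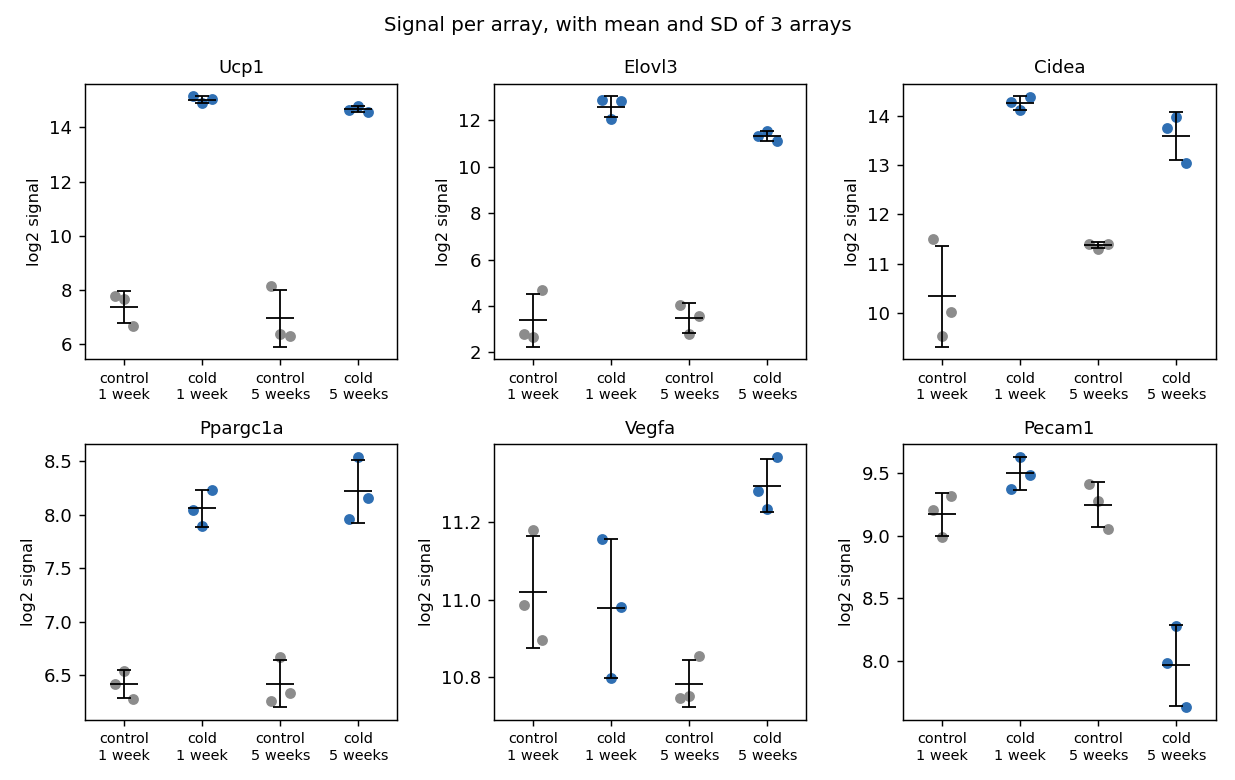
Log2 signal of 6 genes on each array (points) in the 4 groups, with the mean and SD of 3 arrays (bars). Ucp1 and Elovl3 lay higher in every cold array than in any control array, by log2 7.65 and 9.21 on average at 1 week and by 7.71 and 7.86 at 5 weeks, whereas Vegfa, on its brightest probe set, differed by -0.04 and 0.51 and Pecam1 by 0.33 and -1.28. Control signals of Elovl3 lay near or below log2 4, so the size of its differences is uncertain.

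The other large rises at 1 week were Acot11 (42.3-fold, SE 0.29 on the log2 scale), which hydrolyses fatty acyl-CoA, Cidea (3.91, SE 0.40), a lipid droplet protein of brown fat, Aspg (3.91, SE 0.13), Clstn3 (3.82, SE 0.28) and Otop1 (3.80, SE 0.44). Kng1, which encodes kininogen, lay below log2 4 in every control array and was at least 10.4-fold higher in the cold. Among the largest falls were S100a9 (-2.42, SE 0.24) and Prtn3 (-2.25, SE 0.38), proteins of myeloid cell granules or cytosol. Ipcef1 (-2.27), Adgrg6 (-2.21), Zfp119b (-2.14), Zfp994 (-2.10), Pxylp1 (-2.09) and Dsc3 (-2.08) also fell. Slc44a2 fell by 2.66 on its brightest probe set, but another of its probe sets gave 0.42, and the other probe sets of Adgrg6 and Dsc3 gave 0.04 and 0.17.

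Of 27 tested genes of the list of thermogenic and brown or beige adipocyte genes, 22 rose and none fell at 1 week (camera adjusted p = 2.75e-14, limma fit; adjusted p = 0.0570 with an estimated correlation). Besides Ucp1 and Fabp3, its members included Letmd1 (log2 2.99, SE 0.14), Slc25a20 (2.70, SE 0.13), the mitochondrial carnitine carrier, and Slc27a2 (3.55, SE 0.18). Dio2, which activates thyroid hormone, was at least 3.32-fold higher. Ppargc1a, a coactivator of mitochondrial gene expression, rose 3.12-fold (log2 1.64, SE 0.16). The genes of fat burning moved with them. In fatty acid oxidation 23 of 26 rose, such as Etfdh (2.28, SE 0.09) and Pdk4 (3.18, SE 0.18), with camera adjusted p = 2.38e-18 and adjusted p = 0.0923 with an estimated correlation. In oxidative phosphorylation 66 of 70 rose, such as Uqcrq (1.62), Uqcrfs1 (2.82-fold) and Ndufv1 (1.48), and Cox7c and Atp5g1 fell (camera adjusted p = 4.30e-32; adjusted p = 0.0923 with an estimated correlation). In the tricarboxylic acid cycle 23 of 25 rose, such as Suclg1 (1.88), Idh3b (1.56), Ogdh (1.52) and Idh3g (1.21), with camera adjusted p = 2.71e-17 and adjusted p = 0.0931 with an estimated correlation.

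Genes that make and store fat rose as well at 1 week. In fatty acid and triglyceride synthesis 23 of 29 rose and 2 fell, with Acacb at 2.15 (SE 0.20), Agpat2 at 1.41, Taldo1 at 1.12 and Pgd at 0.85 (camera adjusted p = 4.53e-09). In the list of lipolysis and lipid droplets 15 of 22 rose and 1 fell, with Plin5 at 3.45 (SE 0.25), Slc27a1 at 1.85 and Plin2 at 1.32 (camera adjusted p = 3.00e-06). In cholesterol synthesis 11 of 17 rose and 2 fell, with Fdps at 1.79, Pmvk at 1.39, Nsdhl at 1.36 and Lss at 1.28 (camera adjusted p = 6.69e-04). With an estimated correlation these gave adjusted p = 0.248, adjusted p = 0.264 and adjusted p = 0.288. Pck1, an enzyme of glycerol synthesis in fat, rose by 0.71 (SE 0.19). The list of white adipocyte identity showed no shift at 1 week (4 rose, 5 fell, 14 did not pass, of 23; camera adjusted p = 0.995, pointing up while the median and mean were negative). In it Nnat, Rarres2 (-0.96) and Psat1 (-0.58) fell and the glucose transporter Slc2a4 rose (1.33). Leptin (Lep) fell by 0.55 (SE 0.15) and Pparg by 0.27 (SE 0.07), whereas Adipoq gave -0.03 (SE 0.07, adjusted p = 0.771).

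Marker genes of immune cells fell at 1 week. Of 26 T and B lymphocyte markers 23 fell and none rose, with Il7r at -1.57 (SE 0.17), Satb1 at -1.35, Cr2 at -0.91 and Cd4 at -0.90 (camera adjusted p = 2.07e-05; adjusted p = 0.408 with an estimated correlation). Of 30 macrophage markers 21 fell, with Ctss at -1.10, C1qb at -1.04 and Mrc1 at -0.99, and C1qa rose (camera adjusted p = 2.72e-05; adjusted p = 0.203 with an estimated correlation). Of 17 interferon response genes 14 fell, with Iigp1 at -1.21, Oasl2 at -1.20, Gbp3 at -1.17 and Oas1a at -0.94 (camera adjusted p = 5.89e-04; adjusted p = 0.469 with an estimated correlation). Of 31 fibroblast and extracellular matrix genes 19 fell and 1 (Lox) rose, with Col15a1 at -1.12, Fn1 at -1.02, Col6a3 at -0.80 and Col5a2 at -0.73 (camera adjusted p = 1.06e-04; adjusted p = 0.248 with an estimated correlation). Of 31 cell cycle genes 15 fell, with Mcm5 at -1.15, Mcm4 at -1.09, Mki67 at -1.04 and Mcm7 at -0.94 (camera adjusted p = 0.0122; adjusted p = 0.553 with an estimated correlation). That last call was lost without control_1wk 3 (median log2 -0.40 of the list) or without cold_1wk 1 (-0.35). The 3' minus 5' signal of the Gapdh control probe sets, a sign of RNA quality, was 0.90, 3.00 and 3.12 in the 1 week controls and between -0.08 and 0.34 in the 1 week cold arrays.

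Blood vessel genes moved in both directions at 1 week. Vegfa, the main growth factor of blood vessels, gave -0.04 (SE 0.11, adjusted p = 0.759), and its other probe set gave 1.53. Of its receptors, Kdr gave 0.03 (SE 0.15, adjusted p = 0.870) and Flt1 0.27 (SE 0.14, adjusted p = 0.139), and the endothelial adhesion gene Pecam1 gave 0.33 (SE 0.16, adjusted p = 0.112). Of 44 angiogenic factors and receptors 4 rose and 17 fell (camera adjusted p = 0.175), and fry, which asks whether a list moves on balance, called it downward (adjusted p = 5.57e-04; median log2 -0.18, and 0.04 with arrays centred on the median of the tested genes), with Cxcl12 at -1.22, Timp2 at -0.97, Jag1 at -0.77 and Timp3 at -0.65. The mean over all probe sets of the gene gave 0.75 for Vegfa, 0.24 for Timp2 and 0.20 for Timp3, so the direction of these depended on the probe set. Of 29 endothelial markers 9 rose and 3 fell (camera adjusted p = 0.0905; fry adjusted p = 0.0786), with Gpihbp1 at 1.73 and Plvap at 1.29 among the rises and Lyve1 at -0.79 and Tek at -0.72 among the falls. Thbs1 was not tested: the 2 probe sets that name it alone reached at most log2 2.51, and 1 more, at 6.61 to 7.80, names Pald1 as well and was left out of the gene tests (-0.71 at 1 week and -0.73 at 5 weeks).

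Of 35 genes of the hypoxia response 15 rose and 8 fell at 1 week (camera adjusted p = 0.0117; adjusted p = 0.0923 with an estimated correlation), a call lost without the filter on dim probe sets (median 0.20, against 0.22). Those that rose most clearly encode enzymes of glycolysis, Pfkl (2.34), Pgk1 (1.72) and Gapdh (1.46), or the oxygen sensor Egln1 (0.97), while Hif1a itself fell by 0.55 (SE 0.10). Control probe sets were not barred from the gene tests. The Gapdh value may therefore come from a Gapdh control probe set, of the kind read here as a sign of RNA quality. Of the 4 tested erythrocyte transcripts 3 rose, Alas2 (0.91), Fech (0.66) and Slc4a1 (at least 1.25-fold), with camera adjusted p = 0.0113 and adjusted p = 0.0989 with an estimated correlation. The member that did not pass was Hbb-b2 (0.10 to 0.48 with single arrays left out), the only globin gene tested of the 11 genes listed. Of 20 skeletal muscle markers Myl1 (1.40, SE 0.29) and Mb (0.89, SE 0.23) rose, with camera adjusted p = 0.00953 and adjusted p = 0.570 with an estimated correlation. The mean signal of this list was log2 9.38 on cold_1wk 2 and between 5.28 and 5.68 on the other 1 week arrays, and without cold_1wk 2 the call was lost, with a median log2 of 0.02 in place of 1.30.

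The remaining lists were not called by camera at 1 week. Their rises, falls and camera adjusted p were 1, 3 and 0.605 for 15 pericyte and smooth muscle markers (Mcam -1.08). They were 1, 1 and 0.327 for the 6 tested of 27 epithelial, epididymal and mesothelial markers (Gpm6a -1.42, with median and test above 0 and mean below). They were 3, 1 and 0.263 for 13 creatine and calcium cycling genes (Gpd2 2.03), and 3, 3 and 0.399 for 11 nerve and glia markers. In the last list S100b, a calcium-binding protein of glia and of fat cells, rose by 3.79 and the sodium channel Scn7a fell by 1.38. The values were 3, 8 and 0.578 for 19 immediate early genes (Cebpd -0.96, Ier3 1.29), and 3, 6 and 0.559 for 19 heat shock and endoplasmic reticulum stress genes (Hspa5 -0.87, Hsp90b1 -0.92). They were 3, 2 and 0.506 for 16 clock genes (Nr1d1 1.63), and 9, 6 and 0.121 for 22 antioxidant genes (Sod2 1.79, Prdx3 1.39, Mt2 -1.07). Of these, fry called the antioxidant (adjusted p = 0.0142), creatine and nerve lists (0.0488 for each) upward and the heat shock (3.30e-04) and immediate early lists (0.0488) downward, and of the lists called by camera at 1 week it left out the muscle list alone (0.255). Adjusted over the list alone, the rises and falls were 22 and 1 for the thermogenic list, 24 and 1 for fatty acid oxidation, 66 and 3 for oxidative phosphorylation and 24 and 3 for fatty acid synthesis. They were 16 and 1 for lipolysis, 1 and 20 for extracellular matrix, 2 and 2 for clock, 10 and 6 for antioxidant and 12 and 2 for cholesterol genes, and equal to the counts over all genes for the other 17 lists.

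**Figure D2:**
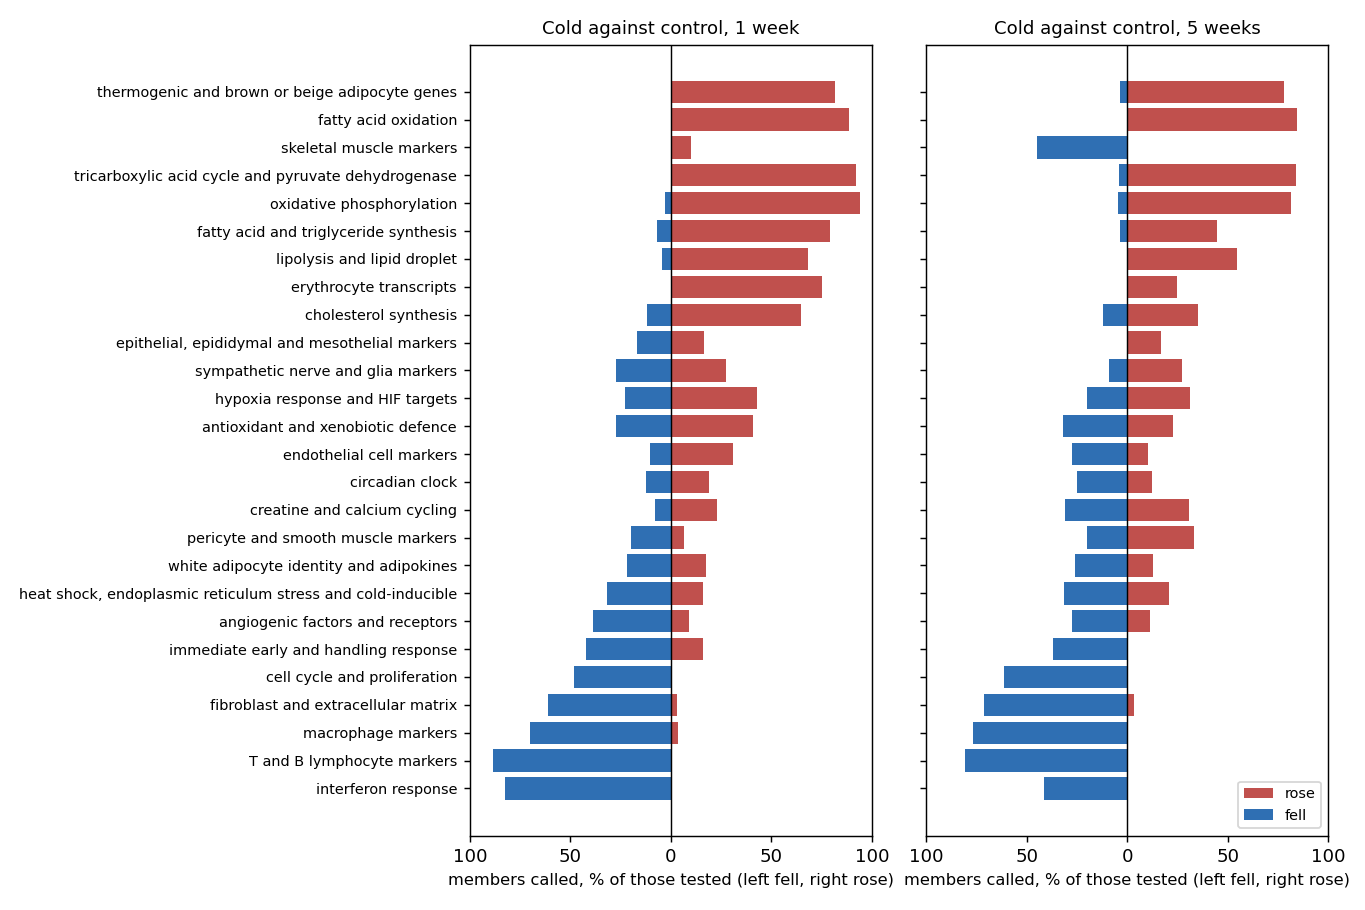
Share of the tested members of each gene list that rose (red, to the right) or fell (blue, to the left) with cold at 1 week and at 5 weeks, in percent of the members tested (limma, Benjamini-Hochberg). Of the 70 oxidative phosphorylation genes 66 rose at 1 week and 57 at 5 weeks, and of the 26 lymphocyte markers 23 and 21 fell.

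Over all genes, 6362 of 12856 changed at 1 week (limma, Benjamini-Hochberg adjusted p under 0.05), 2305 up and 4057 down, of which 519 and 820 changed at least 2-fold. The number fell to 3036 with the Gapdh 3' minus 5' signal as a covariate and to 2885 without control_1wk 2 and 3, the arrays with the highest values of it, where the single control left is assumed to vary like the other groups. The share of rises was 36.2%, and 63.9% after the arrays were centred on the median of the tested genes, which moved the median of all genes from -0.08 to 0.14; with it Pparg (-0.05) and Lep (-0.33) were no longer called, Flt1 (0.49) and Pecam1 (0.55) were, as under quantile normalization (0.43 and 0.46), and the medians of the angiogenic, white adipocyte and heat shock lists turned positive. With the Gapdh covariate 23 of the 119 named genes called at 1 week lost the call. Pck1 went from 0.71 to 0.38 and Slc2a4 from 1.33 to 0.52, whereas Zfp119b (-1.92), Lep (-0.48), Pparg (-0.27), Hif1a (-0.43) and Psat1 (-0.45) stayed closer to their values without it.

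The second comparison asked the same after 5 weeks. Ucp1 was 210-fold higher (log2 7.71, SE 0.42) and Elovl3 at least 159-fold higher (log2 7.86, SE 0.49). Slc27a2, a fatty acid transporter and acyl-CoA ligase, was at least 21.5-fold higher, and S100b rose by 5.22 (SE 0.17). The largest falls were in genes of skeletal muscle: the myosin Myh1 was at least 104-fold lower in the cold and the actin Acta1 fell by 6.54 (SE 1.43). The muscle list had a mean signal of log2 7.68, 7.96 and 7.86 in the 5 week controls and between 5.03 and 5.17 in the 5 week cold arrays. It also stood at 5.31 to 5.68 in the 1 week controls.

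The other large rises at 5 weeks were Fabp3 (5.37, SE 0.28), Acot11 (5.20, SE 0.29), Cox7a1 (4.48, SE 0.30), Pdk4 (4.15, SE 0.18), an inhibitor of pyruvate dehydrogenase, and Plin5 (4.01, SE 0.25). Mfsd4b1 was at least 7.09-fold higher. The other muscle genes among the largest falls were Tnnc2 (at least 59.8-fold lower), Tnnt3 (at least 13.3-fold lower), Atp2a1 (-3.68, SE 1.13), Mylpf (-3.64, SE 1.10) and Ttn (-2.52, SE 0.59). Apobec2, a gene of striated muscle, was at least 4.19-fold lower, and its other probe set gave 0.20. Outside muscle, Il10ra, the interleukin 10 receptor, was at least 4.67-fold lower and the complement gene C1qa fell by 2.62 (SE 0.57). C1qa gave -3.18 to -2.01 with single arrays left out, and -0.33, not called, with the Actb 3' minus 5' signal as a covariate. Of 20 muscle markers 9 fell, Mb (-2.23) and Neb (at least 1.30-fold lower) among them, and 13 fell adjusted over the list alone (camera adjusted p = 6.29e-04; adjusted p = 0.584 with an estimated correlation). With the muscle list mean as a covariate Mylpf gave -0.05 and Tnnt3 -0.08, and neither was called; both are on that list, so the covariate takes out their change by construction. With the 3 control_5wk arrays averaged and counted as 1, Acta1, Tnnc2, Tnnt3, Atp2a1, Mylpf, Ttn, Neb, Apobec2, C1qa and Cidea were no longer called; their fitted values stayed the same by construction, and the error grew. Leaving out any single array of the comparison except cold_5wk 3 ended the call of Mylpf (-3.40 to -3.74 in those cases), leaving out any of the 6 ended that of Tnnt3 (-4.69 to -4.77), and leaving out any control_5wk array or cold_5wk 3 ended that of Atp2a1 (-3.09 to -3.77).

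**Figure D3:**
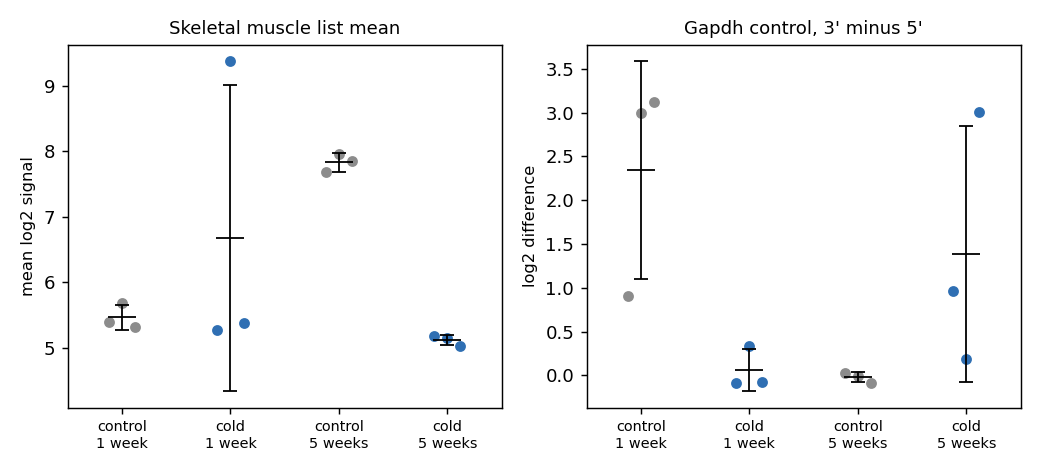
Left, mean log2 signal of the 20 tested skeletal muscle markers on each array; right, 3' minus 5' log2 signal of the Gapdh control probe sets, where points are arrays and bars the mean and SD of 3. The muscle mean lay between 7.68 and 7.96 in the 5 week controls and at 9.38 on cold_1wk 2, and the Gapdh difference was 3.00 and 3.12 on control_1wk 2 and 3 and 3.01 on cold_5wk 3.

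The thermogenic list kept its rise at 5 weeks, with 21 of 27 genes up and 1, Tmem26 (-1.43), down (camera adjusted p = 6.14e-16; adjusted p = 0.0394 with an estimated correlation, the only list call of the 1 week and 5 week comparisons that held under it). Letmd1 (2.75), Slc25a20 (2.70), Ppargc1a (1.79, SE 0.16) and Cidea (2.22, SE 0.40) rose, and Dio2 was at least 5.97-fold higher. In fatty acid oxidation 22 of 26 rose (Etfdh 2.36; camera adjusted p = 2.32e-18). In oxidative phosphorylation 57 of 70 rose (Ndufv1 1.53, Ndufs1 1.39, Cycs 1.11) and 3 fell, Cox6a2, which muscle expresses, Atp5g1 and Atp5g3 (camera adjusted p = 2.52e-25). In the tricarboxylic acid cycle 21 of 25 rose (Idh3b 1.49, Idh3g 1.47, Ogdh 1.42, Fh1 1.27) and Pcx fell (camera adjusted p = 7.05e-16). These 3 gave adjusted p = 0.127 with an estimated correlation. In fatty acid and triglyceride synthesis 13 of 29 rose and Srebf1 fell (Acacb 1.91, Elovl6 1.42, Pgd 0.75, Acly 0.61; camera adjusted p = 0.00123; adjusted p = 0.529 with an estimated correlation). In lipolysis and lipid droplets 12 of 22 rose (Angptl4 1.40, Slc27a1 1.15, Plin2 1.13, Pck1 1.01; camera adjusted p = 3.94e-05; adjusted p = 0.369 with an estimated correlation).

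Immune and matrix genes were lower at 5 weeks too. Of 26 lymphocyte markers 21 fell, with Coro1a at -1.82, Cd37 at -1.80, Ccr7 at -1.43 and Cd4 at -1.31 (camera adjusted p = 2.16e-08; adjusted p = 0.288 with an estimated correlation). Of 30 macrophage markers 23 fell and none rose, with Folr2 at -1.85, Timd4 at -1.56, Aif1 at -1.38 and Lyz2 at -1.01 (camera adjusted p = 2.79e-08; adjusted p = 0.127 with an estimated correlation). Of 31 matrix genes 22 fell and Lox rose, with Col6a1 at -0.92, Col1a2 at -0.88, Col6a3 at -0.85 and Col6a2 at -0.82 (camera adjusted p = 2.64e-06; adjusted p = 0.156 with an estimated correlation). Of 31 cell cycle genes 19 fell, with Birc5 at -1.29, Ccna2 at -1.27, Mcm6 at -1.27 and Pcna at -1.05 (camera adjusted p = 5.34e-05; adjusted p = 0.431 with an estimated correlation). Of 19 immediate early genes 7 fell, with Ier2 at -1.55, Klf2 at -1.20, Cebpd at -1.06 and Junb at -0.77 (camera adjusted p = 0.0163; adjusted p = 0.381 with an estimated correlation), a call lost at a filter level of log2 6 (median -0.37, against -0.27). The Actb 3' minus 5' signal was 2.03, 1.84 and 2.80 in the 5 week cold arrays and between 1.04 and 1.16 in the 5 week controls; the Gapdh difference was 0.96, 0.19 and 3.01 against -0.08 to 0.03.

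The vessel genes named individually went both ways at 5 weeks. Vegfa rose by 0.51 (SE 0.11) and Flt1 by 0.88 (SE 0.14), Pecam1 fell by 1.28 (SE 0.16), and Kdr gave -0.24 (SE 0.15, adjusted p = 0.221). The other probe set of Vegfa gave -0.37, and the mean of both, at 0.07, was not called. Of 44 angiogenic genes 5 rose and 12 fell (camera adjusted p = 0.178), and fry called the list downward (adjusted p = 0.0122), with Fgf1 2.83-fold higher, Col18a1 at -1.03, Cxcl12 at -0.80 and Mmp14 at -0.79. Of 29 endothelial markers 3 rose and 8 fell (camera adjusted p = 0.270), and fry called it downward too (adjusted p = 0.0355), with Plvap at -1.25 and Lyve1 at -0.66. The medians of these lists, -0.13 and -0.12, were 0.03 and 0.04 with arrays centred on the tested genes. With the Actb 3' minus 5' signal as a covariate Vegfa gave 0.27, Flt1 0.51 and Pecam1 -0.55, and none of the 3 was called.

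Lep fell by 0.89 (SE 0.15) at 5 weeks, whereas Adipoq gave -0.15 (SE 0.07, adjusted p = 0.143) and Pparg -0.08 (SE 0.07, adjusted p = 0.442). In the white adipocyte list 3 of 23 rose and 6 fell (camera adjusted p = 0.252), with Mest at -1.99, Nnat at -1.90, Rarres2 at -1.10 and Nampt at 0.67. In the hypoxia list 11 of 35 rose and 7 fell (camera adjusted p = 0.0637), with Pfkl at 1.60, Pgk1 at 1.25, Egln1 at 1.06 and Mxi1 at 0.89. Hif1a fell by 0.32 (SE 0.10), a call that did not hold without control_5wk 1, 2 or 3 or without cold_5wk 1 or 2 (-0.29 to -0.36). In the erythrocyte list Fech rose by 0.75 and the other 3 tested genes did not pass (camera adjusted p = 0.0431; adjusted p = 0.156 with an estimated correlation), and this list call was lost under quantile normalization (median 0.44, against 0.35), at a filter level of log2 6 (0.43) and with arrays centred on the tested genes (0.51), where the medians were higher, and without control_5wk 3, cold_5wk 1 or cold_5wk 2 (0.31 to 0.34). The lists not called by camera gave, as rises, falls and camera adjusted p, 0, 7 and 0.0698 for interferon (Oas1a -1.42, Bst2 -1.30), and 6, 2 and 0.0798 for cholesterol synthesis (Dhcr7 0.94). They gave 5, 3 and 0.899 for pericyte markers (Mcam -0.99, Notch3 0.69), and 1, 0 and 0.388 for epithelial markers (Cldn3 0.61). They gave 4, 4 and 0.708 for creatine and calcium cycling (Gpd2 2.45, Ckb -0.86), 3, 1 and 0.0663 for nerve and glia (Pmp22 -0.50), and 4, 6 and 0.847 for heat shock (Hsp90b1 -0.75, Dnajb9 0.57). They gave 2, 4 and 0.911 for clock (Cry1 1.09) and 5, 7 and 0.910 for antioxidant genes (Mt2 -1.54, Sod2 1.25). Of the lists that camera did not call at 5 weeks, fry also called the hypoxia (adjusted p = 4.26e-05), nerve (6.63e-04), creatine (0.0268) and cholesterol lists (0.0355) upward and the white adipocyte list downward (0.0194). At 5 weeks camera pointed up in the creatine list, whose median and mean were negative, and in the antioxidant list, whose mean was negative, and down in the heat shock list, whose median was positive. Adjusted over the list alone, the rises and falls were 22 and 1 for the thermogenic list, 23 and 0 for fatty acid oxidation, 58 and 3 for oxidative phosphorylation, 15 and 2 for fatty acid synthesis and 13 and 0 for lipolysis. They were 5 and 4 for pericyte, 0 and 22 for lymphocyte, 0 and 20 for cell cycle, 3 and 0 for erythrocyte, 1 and 7 for interferon and 9 and 4 for cholesterol genes; the other lists but muscle gave the counts over all genes.

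Over all genes, 4654 changed at 5 weeks (limma, Benjamini-Hochberg), 1925 up and 2729 down, with 345 and 455 at least 2-fold. The number was 2583 with the muscle mean as a covariate, 1608 with the control_5wk arrays counted as 1 and 795 with the Actb 3' minus 5' signal as a covariate, which ended the call of 57 of the 115 named genes called at 5 weeks. The share of rises was 41.4%. It was 53.1% under quantile normalization, 51.4% without the filter, 50.9% with the muscle covariate, 61.0% with the Actb one and 66.6% with arrays centred on the tested genes, where the median of all genes moved from -0.03 to 0.13 and the medians of the angiogenic, white adipocyte, endothelial, interferon, clock, pericyte and creatine lists turned positive.

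Most genes called at 1 week moved the same way at 5 weeks. Of them, 80.6% had the same sign at 5 weeks. Rises at both times numbered 1103, against 345 if the lists were unrelated, and falls 1610, against 861, while 210 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.553 (jackknife SE 0.105) and rho = 0.526. Averaged over both times, 7161 genes changed (limma, Benjamini-Hochberg), 2749 up and 4412 down. The balance turned with arrays centred on the tested genes, with 5120 up and 2726 down, without the filter, with 5605 up and 4474 down, and at a 2-fold minimum, with 354 up and 348 down.

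**Figure D4:**
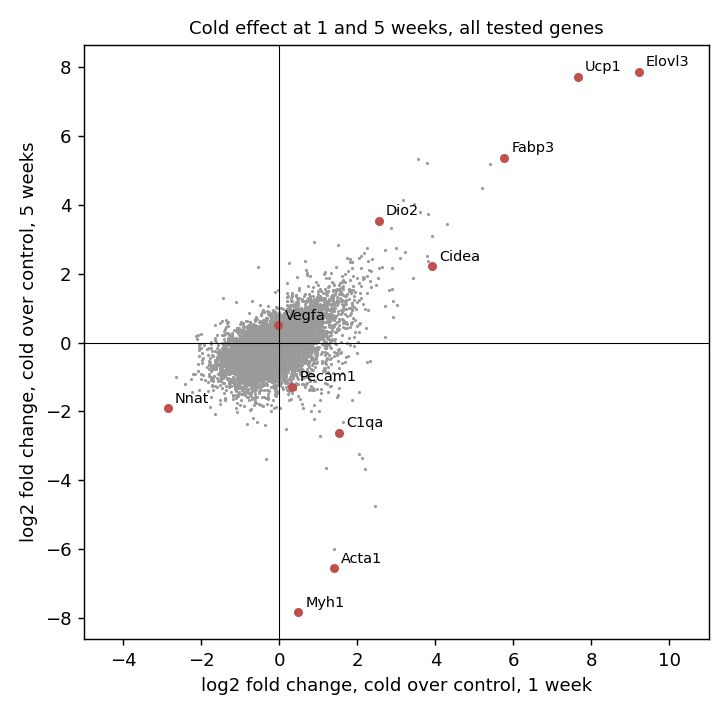
Log2 fold change of cold over control at 1 week (horizontal) and at 5 weeks (vertical) for 12856 genes, with 11 genes named. Elovl3 and Ucp1 rose at both times, whereas Myh1 and Acta1 lay far down at 5 weeks; r across genes was 0.553.

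The third comparison asked whether the cold effect differed between 5 weeks and 1 week, as the difference of the 2 effects. Among called genes the lowest differences were those of muscle genes. With signals below log2 4 set to 4 they were -7.94 for Acta1 (SE 2.02, no signal below 4), -7.32 for Tnnc2, -7.08 for Myh1, -5.88 for Tnnt3 and -5.29 for Atp2a1; as fitted the last 4 were -7.38, -8.30, -7.19 and -5.87. Without cold_1wk 2 the fitted values were -5.59 for Acta1, -4.77 for Tnnc2, -6.73 for Myh1, -4.84 for Tnnt3 and -4.12 for Atp2a1, all called. The call of Acta1 ended without control_5wk 2 (-7.87), that of Tnnc2 on leaving out any of the control or cold_5wk arrays (-6.83 to -7.83), that of Tnnt3 without control_1wk 2 or 3, any control_5wk array, cold_5wk 1 or cold_5wk 3 (-7.07 to -7.22), and that of Atp2a1 without control_1wk 2 or 3, control_5wk 1 or 2 or cold_5wk 3 (-5.28 to -6.01). The highest differences were those of Kcnq1ot1 (2.73, SE 0.66), a noncoding RNA of an imprinted locus, the chemokine receptor Ackr4 (2.72, SE 0.52), Zfp119b (2.33), Cdh19 (2.30) and Adgrg2 (2.28); other probe sets gave -0.50 to 0.86 for Kcnq1ot1 and 0.11 for Adgrg2. The call of Zfp119b ended without control_1wk 2, control_5wk 1 or cold_5wk 3 (2.14 to 2.29). That of Cdh19 ended on leaving out any of the control or cold_5wk arrays (2.12 to 2.47), and without cold_1wk 2 its value was 1.53. Ucp1 gave 0.06 (SE 0.60, adjusted p = 0.956) and Elovl3 -1.35 (SE 0.69, adjusted p = 0.188). The size of the Elovl3 value is uncertain, as its control signals lay near or below log2 4 (2.67 to 4.70 at 1 week and 2.79 to 4.06 at 5 weeks). Vegfa gave 0.55 (SE 0.15, adjusted p = 0.0283) on its brightest probe set, but its other probe set gave -1.91 and the mean of both, not called, -0.68, so the direction depended on the probe set. The call of Vegfa also ended without control_1wk 2, control_5wk 1 or 2 or cold_5wk 3 (0.47 to 0.54). Pecam1 gave -1.61 (SE 0.23, adjusted p = 0.00427).

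In oxidative phosphorylation the effect lay lower at 5 weeks for 25 of 70 genes and higher for none (median -0.28, camera adjusted p = 5.01e-06); among them Cox6a2 went from 0.72 at 1 week to -0.85 at 5 weeks. It lay lower for 9 of 29 genes of fatty acid synthesis and higher for none (camera adjusted p = 2.02e-04). The effect lay lower at 5 weeks for 8 endothelial markers and higher for 2 of 29, and likewise for 8 and 2 of 22 antioxidant genes (camera adjusted p = 0.0223 for each). It lay lower for 10 of 20 muscle markers (camera adjusted p = 3.65e-08), with a median of -3.31, and of -1.97 without cold_1wk 2, where the list was still called. Without control_1wk 3 the antioxidant list was not called (-0.22, against -0.21 with all arrays and -0.14 without cold_1wk 2), and without control_1wk 1 the median of fatty acid synthesis went from -0.25 to -0.47. Adjusted over the list alone, the numbers higher and lower were 2 and 29, 0 and 10, 4 and 10, 2 and 8 and 0 and 16 for these lists. All 5 gave adjusted p = 0.811 with an estimated correlation, none was called by fry, and the other 21 lists were not called.

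The effect differed for 2552 genes (limma, Benjamini-Hochberg), 1474 higher and 1078 lower at 5 weeks. The balance turned with arrays centred on the tested genes (1126 higher, 1337 lower), with the mean of the probe sets of a gene (935 and 1302) and at a 2-fold minimum (311 and 386). With the Gapdh 3' minus 5' signal as a covariate 3 genes were called, with the Actb one 0 (limma, with 1004 at an unadjusted p under 0.05), and with the muscle mean 867; the number was 1 with the control_5wk arrays counted as 1 and 133 without control_1wk 2 and 3. It was 1456 without control_1wk 2, 1390 without control_5wk 1, 1383 without control_5wk 2 and 1584 without cold_5wk 3.

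The last comparisons set 5 weeks against 1 week within each temperature, as log2 5 weeks over 1 week. Genes are ranked here only among called genes whose arrays of the 2 weeks did not overlap. In the cold, Tmem242 (-2.82, SE 0.29), Rraga (-2.60, SE 0.19), Spr (-2.33), Aatk (-2.24) and Hsd17b12 (-2.05) fell most. A variable-region gene of the antibody kappa chain (2.22), the clock repressor Nr1d1 (2.12, SE 0.35), Zfp119b (2.07), Vnn1 (2.05) and Ackr4 (2.00) rose most. The other probe set of Tmem242 gave 0.27. Among lists, 34 of 70 oxidative phosphorylation genes were lower at 5 weeks (camera adjusted p = 3.03e-06), as were 11 of 17 cholesterol genes (3.25e-04), 9 of 29 fatty acid synthesis genes (3.66e-05), 10 of 25 tricarboxylic acid cycle and 9 of 26 fatty acid oxidation genes (0.00577 for each) and 2 of 20 muscle markers (0.00283). Of them 2, 1, 0, 1, 1 and 0 genes were higher. Adjusted over the list alone, 35, 12, 9, 10, 12 and 2 were lower and 3, 1, 0, 2, 3 and 0 higher. These lists gave adjusted p = 0.967 with an estimated correlation; fry called the first 3 (adjusted p = 0.0353, 0.0163 and 0.0389) and also the hypoxia list downward (0.0353; camera adjusted p = 0.242). The muscle list was not called without cold_1wk 2 (median -0.13, against -1.65), nor were fatty acid oxidation and the tricarboxylic acid cycle under quantile normalization (-0.13 and -0.14, against -0.21 for each); without cold_1wk 3 the last had a median of -0.14, against -0.21. In all 3535 genes changed in the cold, 1986 up and 1549 down (limma, Benjamini-Hochberg), a balance that turned with arrays centred on the tested genes (1593 up, 1996 down) and with the mean of the probe sets of a gene (1476 and 1713). The count was 1885 with the Gapdh covariate, 5 with the Actb covariate, 2130 with only the 6 cold arrays in the model and 2054 without cold_5wk 3.

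In the controls, among called genes without such overlap, Myh1 (6.64, SE 1.21), Nr1d1 (3.30, SE 0.35), Apobec2, the antibody gene Igha (2.83, SE 0.17) and the clock output gene Dbp (2.66, SE 0.17) rose most. Acta1, at 6.88 to 7.63 in control_1wk and 11.9 to 12.2 in control_5wk, was not called. By the same rule Rraga (-2.20, SE 0.19), the clock-linked repressor Nfil3 (-2.11, SE 0.23), Mup10, Hsd17b12 (-1.92) and Slc27a2 fell most. Myh1 was at least 57.6-fold higher, Apobec2 at least 4.19-fold higher, Mup10 at least 2.67-fold lower and Slc27a2 at least 1.93-fold lower when signals below log2 4 were set to 4. Of 16 clock genes 5 rose and 4 fell (camera adjusted p = 0.115). Of 20 muscle markers 3 rose (camera adjusted p = 3.27e-10), of 29 endothelial markers 2 (0.00585), and of 26 lymphocyte markers 1 (0.0429), and 1 of 17 interferon genes fell (0.00539); the 31 cell cycle genes were called upward as a list (0.00539) with no member called. Adjusted over the list alone, 12, 6 and 1 rose, 5 interferon genes and 1 lymphocyte marker fell, and of clock genes 6 rose and 4 fell. With an estimated correlation these gave adjusted p = 0.816, and adjusted p = 0.875 for lymphocytes, and fry called no list. The lymphocyte list (median 0.13) was not called without control_1wk 1 (-0.04), control_5wk 1 (0.10) or control_5wk 3 (0.14) or at a filter level of log2 6 (0.14), and its median was 0.29 without control_1wk 3. The cell cycle list (0.15) was not called without control_1wk 1 (0.11) or 2 (0.08), with 0.34 without control_1wk 3, and the interferon list (-0.43) was not called without control_1wk 3 (-0.12). The endothelial list (0.08) gave 0.13 without control_1wk 1. In all 328 genes changed, 165 up and 163 down (limma, Benjamini-Hochberg). The balance depended on the setting, with for example 133 up and 255 down with centred array medians and 266 up and 146 down with the mean of the probe sets of a gene. This count was 841 without control_1wk 1, 93 without control_1wk 2, 134 without control_1wk 3, 69, 61 and 84 without control_5wk 1, 2 and 3, 2039 with array weights, 206 with the muscle covariate, 30 with the Gapdh covariate, 63 with replicate numbers as blocks, 48 without control_1wk 2 and 3 and 13 with the control_5wk arrays counted as 1.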

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

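The tests of muscle content, muscle lowered by cold, shared RNA, sampling time and age, the covariates and the alternatives to the interaction of single genes were chosen only after the results they measure were seen; the idea of the RNA quality test came after the counts with the Gapdh covariate were seen, and the tests with reassigned arrays were set beforehand.

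The cold effect differed between 5 weeks and 1 week for 2552 genes by the interaction test, and for 5 gene lists, whose median log2 differences were -0.28 for oxidative phosphorylation, -0.25 for fatty acid and triglyceride synthesis, -0.27 for endothelial markers, -3.31 for skeletal muscle markers (-2.91 with signals below log2 4 set to 4) and -0.21 for antioxidant genes. None of the 5 lists was called with an estimated correlation (adjusted p = 0.811 for each) or by fry. Among named genes the log2 difference was -0.87 for Kng1, -0.82 for Aspg, -1.44 for Clstn3, 1.67 for Slc44a2, 1.23 for S100a9, 1.21 for Ipcef1, 2.33 for Zfp119b, 2.19 for Zfp994 and 1.48 for Pxylp1. It was 0.55 for Vegfa, -1.61 for Pecam1, 1.78 for Slc27a2, 1.42 for S100b, 0.97 for Pdk4, -3.04 for Il10ra and -4.15 for C1qa. It was 2.73 for Kcnq1ot1, 2.72 for Ackr4, 2.30 for Cdh19 and 2.28 for Adgrg2. In muscle genes it was -8.30 for Myh1, -7.94 for Acta1, -7.38 for Tnnc2, -7.19 for Tnnt3, -5.87 for Atp2a1, -4.84 for Mylpf, -3.75 for Apobec2 and -2.70 for Ttn. Where signals lay below log2 4, setting them to 4 gave -0.93 for Kng1, 0.87 for Slc27a2, -1.96 for Il10ra, -2.63 for Apobec2, -7.08 for Myh1, -7.32 for Tnnc2, -5.88 for Tnnt3, -5.29 for Atp2a1, 2.04 for Zfp119b, 2.16 for Zfp994 and 2.12 for Cdh19. Other probe sets gave the opposite sign for Vegfa (-1.91), Slc44a2 (-1.23 and -0.01) and Apobec2 (0.15), and for 1 or more of those of Kcnq1ot1 (-0.50 to 0.86). None of these 28 genes was called with the Gapdh or the Actb covariate, nor with control_5wk counted as 1 array, which by construction leaves the differences as they are and raises their errors. The call of Kng1 ended on leaving out any array but cold_1wk 2, cold_5wk 2 or cold_5wk 3 (-0.68 to -0.90 in those cases), and that of S100a9 any but control_1wk 1, control_1wk 2, cold_1wk 3 or cold_5wk 3 (1.14 to 1.27). That of Clstn3 ended without control_1wk 3, cold_1wk 1 or 3 or control_5wk 1 or 2 (-1.30 to -1.45), and that of Pdk4 without control_1wk 3, cold_1wk 3 or control_5wk 2 or 3 (0.86 to 0.93). Those of Mylpf (-4.60 to -5.01) and Ttn (-2.55 to -2.94) ended on leaving out any of the control or cold_5wk arrays, and without cold_1wk 2 they were called at -3.03 and -1.79. Among the 4132 probe sets above the filter that name no gene or several, 1680 changed with cold at 1 week and 998 at 5 weeks.

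The control_5wk arrays held skeletal muscle transcripts at similar levels, with Acta1 at log2 11.9 to 12.2, and lay closer together than the other groups (median SD 0.0929 against 0.132 to 0.156). A lowering of muscle transcripts by cold at both times stays open: at 1 week the muscle mean of 1 of the 3 cold arrays lay below all controls and Acta1 did on 2 of them, while on cold_1wk 2 Acta1 reached 13.3 and Ckm 11.6, but the muscle mean of the 1 week controls stood just 0.35 over that of the 5 week cold arrays, against 2.72 for the 5 week controls, so a fall as large could not have shown. A lowering by cold at 5 weeks alone was not tested and stays open too. Muscle carried along with the fat stays open as well. Of the 23 genes at least 4-fold higher on cold_1wk 2 than on the other 1 week cold arrays, 16 are on the muscle list and so restate the pattern. Of the 7 others, too few to decide, 2 (28.6%, Apobec2 and Smpx) were at least 2-fold higher in control_5wk than in control_1wk. Among the genes outside those 23 it was 0.65%. Pygm (log2 0.88), Ldb3 (0.80), Pgam2 (0.58), Lig1 (0.26) and Slc15a2 (0.04) were higher in control_5wk by less than 2-fold. A shared RNA or pool of animals stays open too, as the values point both ways: the spread of 15 antibody genes stood at percentile 56 of random gene sets of like level in control_5wk (77.3 when matched to the level in that group), against 100, 100 and 99.8 in control_1wk, cold_1wk and cold_5wk, but matched that way the thermogenic list stood at 99.6 in control_5wk, extracellular matrix at 99.4 and muscle at 100, and Ucp1 ran from 6.32 to 8.15, wider than in control_1wk (6.69 to 7.77).

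The interaction of 2552 genes exceeded the 1545 of the highest other of 100 drawn assignments of weeks within each temperature, of which 1, the real one, reached it; this excludes chance only if the control_5wk arrays are separate replicates, since with them counted as 1 the interaction was 1 gene. RNA quality may account for part of it: across genes, the slope on the Gapdh 3' minus 5' signal within groups correlated with the interaction at r = 0.53 (0.43 without control_1wk 1 in the slope), and 87.1% of called genes had the sign it predicts. With Gapdh the agreement lay at 1 week (r = 0.51 with the cold effect, its sign turned) and not at 5 weeks (r = -0.04), though the Gapdh signal was higher in cold_5wk than in control_5wk (1.39 against -0.02). The size that the Gapdh slope predicts was smaller, a median of 0.27 against 0.80. The slope on the Actb signal correlated with the interaction at r = 0.52 and with the Gapdh slope at r = 0.78, and was not split by week. With the Gapdh covariate the median difference of the 2552 genes went from 0.80 (median SE 0.19) to 0.49 (0.25) and with the Actb covariate to 0.50 (0.30), while 2532 and 2519 kept their sign; 3 and 0 genes were called (limma; 1391 and 1004 at an unadjusted p under 0.05), as the differences shrank and their errors grew. The covariates overlap with the groups. Actb was not raised in control_1wk (1.22 to 1.35) as Gapdh was, but it was in cold_5wk (1.84 to 2.80, against 1.04 to 1.16 in control_5wk). A true change with the duration of cold stays open, untested.

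Clock genes changed between the weeks in the controls, 9 of 16 (Fisher's exact p = 4.02e-11 against 2.55% of all genes), with Nr1d1 at 3.30, Dbp at 2.66, Nfil3 at -2.11 and Arntl at -1.10. Fisher's test treats genes as independent, which they are not, so its p does not measure the spread between arrays. The planned camera test, which looks for a shift in 1 direction, did not call this list (5 rose, 4 fell, camera adjusted p = 0.115). Sampling at different times of day may account for the change of the clock genes. Of the 9, 7 moved the same way between the weeks in the cold, and 5 of them, Nr1d1 (2.12), Nr1d2 (1.88), Dbp (1.70), Nfil3 (-1.23) and Arntl (-0.89), were called there too. Clock (-0.58 in controls, 0.12 in the cold) and Bhlhe40 (1.40, -0.40) did not. Age or time in housing cannot be told apart from it, since both differ between the weeks in cold and control alike (Spearman rho 0.65 between them over the 16 genes).

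Cold against control over both times changed 7161 genes, and the highest of the other of 100 drawn splits within each week 3236, so only 1 split, the real one, reached the count, which excludes chance at that resolution if the arrays of a group are separate replicates (5125 genes with control_5wk counted as 1). For each comparison of 3 with 3 arrays the 10 splits are too few for a share under 0.05, with 1 split as large, the real one: 6362 genes against at most 2 in another split for cold at 1 week, 4654 against 0 at 5 weeks, 3535 against 0 between weeks in the cold and 328 against 1 in the controls.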

How the results depend on the processing

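The covariates, the centring on tested genes, the arrays left out for Gapdh the averaging of control_5wk and the alternatives to the interaction of single genes were chosen after seeing the data. Of the values of named genes at 1 or 5 weeks under alternatives, 5489 kept direction and side of the threshold, 242 lost the call, 39 gained it and 21 turned. Of the values of the interaction of 28 genes, 579 kept theirs, 219 lost the call and 4 turned. Lists were followed only where they were called, by the call and the direction of the test: of the values of the 28 list calls at 1 and 5 weeks 352 kept theirs and 40 lost the call, of the 5 of the interaction 89 and 11, and of the 11 between weeks 125 and 29, and in none of these did the test turn, though the median of the lymphocyte list between weeks in controls went from 0.13 to -0.04 without control_1wk 1. These counts include the losses with an estimated correlation. The called lists were not refitted with the Gapdh, Actb or muscle covariate, without the arrays left out for Gapdh, or with control_5wk averaged. Whether the list calls hold under those settings, which lowered gene counts, was therefore not tested. Lists not called were followed under the scalings alone, where medians turned at 1 and 5 weeks. Signal near background limits what dim probe sets can show, and where no construction is named the cause was not tested.

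Counting all probe sets, which are more numerous than genes, gave 11889 at 1 week, 8270 at 5 weeks, 13170 for both, 5220 for the interaction, 7554 between weeks in cold and 888 in controls. A 2-fold minimum, which can only lower a count, gave 1339, 800, 702, 697, 355 and 85. The Gapdh covariate gave 3036 at 1 week, 3 for the interaction, 1885 between weeks in cold and 30 in controls. The Actb covariate gave 795 at 5 weeks, 0 for the interaction (limma; 1004 at an unadjusted p under 0.05) and 5 between weeks in cold. The muscle covariate gave 2583 at 5 weeks, 867 for the interaction and 206 between weeks in controls. With control_1wk 2 and 3 left out, and so fewer arrays, the counts were 2885 at 1 week, 133 for the interaction and 48 between weeks in controls. With control_5wk counted as 1 array, the single one assumed to vary like the others, they were 1608 at 5 weeks, 1 and 13. Averaging control_5wk was not run at 1 week or between weeks in cold, although those arrays enter the shared estimate of the spread. With only the arrays of the comparison the counts were 5179 at 1 week, 5145 at 5 weeks and 2130 between weeks in cold. Array weights gave 2039 and replicate blocks 63 between weeks in controls.

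Leaving out each array of the comparison, the count ranged from 5311 to 6366 at 1 week and 3513 to 4025 at 5 weeks. It ranged from 6427 to 7332 for both and 1383 to 3022 for the interaction. Between weeks it ranged from 2054 to 3368 in cold and 61 to 841 in controls. The correlation of effects ranged from 0.512 to 0.615. Arrays outside a comparison, which also enter its estimate of the spread, were not left out. The interaction was 1456 without control_1wk 2, 1390 and 1383 without control_5wk 1 and 2 and 1584 without cold_5wk 3; weeks in cold gave 2054 without cold_5wk 3. Weeks in controls gave 841, 93 and 134 without control_1wk 1, 2 and 3 and 69, 61 and 84 without control_5wk 1, 2 and 3.

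Values that turned direction were small in the gene's own result, except those of Timp2, Timp3, Mal and Dbh and of the interaction. The mean of a gene's probe sets, which disagree, gave log2 0.75 for Vegfa, 0.24 for Timp2 and 0.20 for Timp3 at 1 week. Centring on tested genes, which shifts every gene up, gave 0.18 for Vegfa and 0.19 for Adipoq at 1 week and 0.011 for Adipoq and 0.078 for Pparg at 5 weeks; quantile normalization gave 0.010 for Adipoq and array-median centring -0.017 for Kdr at 1 week. In the interaction the mean of probe sets gave -0.68 for Vegfa, and the muscle covariate, which takes out the change of its own list by construction, 0.25 for Tnnc2, 0.36 for Mylpf and 0.0073 for Ttn, all on that list. The muscle covariate gave 0.034 for Vegfa at 1 week and -0.0051 for Svs5 and -0.084 for Hbb-b2 at 5 weeks. The Gapdh covariate gave 0.011 for Vegfa and -0.12 for Kdr, and leaving out control_1wk 2 and 3 gave -0.21 for Kdr, at 1 week. The Actb covariate gave -0.023 for Mal and -0.12 for Dbh at 5 weeks. Leaving out single arrays, Vegfa at 1 week ranged from -0.13 to 0.048 and Kdr from -0.0843 to 0.15.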

Other observations

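The tests of gene families below were chosen after the data were seen, as groups of genes that share a symbol stem and have at least 12 tested members (110 families, camera and limma, Benjamini-Hochberg over families). Not all called families are described. At 1 week camera also called Arhgap (adjusted p = 0.0141), Trim (0.0232) and Snhg (0.0267) downward and Krt (0.0232) and Fbxw (0.0347) upward. It called Cd, Cox and Ndufa at both times, and Ccl, Col and Cyp at 5 weeks. With an estimated correlation none of these was called.

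Genes of the mitochondrial ribosome, which makes the proteins encoded in mitochondria, rose with cold. Of 47 Mrpl genes 40 rose and none fell at 1 week (camera adjusted p = 3.59e-15), and 21 rose and 4 fell at 5 weeks (7.20e-06). Of 29 Mrps genes 25 rose at 1 week (1.50e-11) and 15 at 5 weeks (8.74e-05), with none falling. Of 14 Timm genes, which import proteins into mitochondria, 11 rose at 1 week (9.36e-07) and 9 rose and 1 fell at 5 weeks (0.00596). Of 14 Pex genes, which build peroxisomes, 10 rose at 1 week (1.14e-04) and 4 at 5 weeks (0.0474). Of 14 Psmd genes of the proteasome 7 rose at 1 week (0.00293), whereas 3 rose and 2 fell at 5 weeks (0.854). With an estimated correlation the 1 week values were adjusted p = 0.305 for Mrpl and Timm, 0.321 for Mrps, 0.373 for Pex and 0.458 for Psmd. The 5 week values were 0.639 for Mrpl, Mrps and Timm, 0.662 for Pex and 0.944 for Psmd, so none of these was called at either time.

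Families with the symbol stems of cytosolic ribosome genes moved the other way. Of 23 Rpl genes 17 fell and 1 rose at 1 week (camera adjusted p = 0.00157), and 16 fell and 2 rose at 5 weeks (6.29e-04). Of 27 Rps genes 16 fell and 1 rose at 1 week (0.00835), and 17 fell at 5 weeks (2.70e-04). Membership went by the symbol stem alone, so the Rps counts may include kinases named after a ribosomal protein. Probes of ribosomal genes can also share sequence with pseudogenes, so the values are less certain. At 1 week 20 of 30 Rbm genes, which bind RNA, fell (2.14e-04), as did 10 of 17 Kdm genes, which remove histone methyl marks (0.00835), and 126 of 274 Zfp genes, with 11 rising (8.52e-04). At 5 weeks these were not called, with 11 of the Rbm genes falling and 1 rising (0.116), 1 of the Kdm genes falling (0.601) and 35 of the Zfp genes falling and 16 rising (0.726). With an estimated correlation the 1 week values were adjusted p = 0.511 for Rpl, 0.458 for Rps, 0.373 for Rbm, 0.305 for Kdm and 0.424 for Zfp, and the 5 week values 0.662, 0.639, 0.684, 0.800 and 0.901. The medians of the families given here with counts kept their sign under all 4 scalings of the arrays, except those of Psmd and Zfp at 5 weeks, which were -0.004 and -0.04 as deposited and 0.153 and 0.116 with arrays centred on the tested genes.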
